A study of Mus musculus with 472 samples.

How the data were processed

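Meningeal cells were dissected from the anterior and posterior cortex of C57BL/6 mice aged 3 or 18 months, dispensed as single cells on the ICELL8 system, and made into libraries with an Illumina Nextera kit, per the labels' protocols. The authors deposited 1 table of raw counts per gene and cell, with 39179 Ensembl gene IDs and 472 cells (356 titled by position and 116 by barcode), per the file headers. STAR 2.7.0a and the build mm10 come from the submitters' processing notes. The program that counted reads per gene, its strand setting and the annotation are not given in the sources used here. The column names mark the position-titled cells as full-length and the barcode-titled cells as 3-prime libraries, per the file headers. No molecular identifiers are mentioned. Symbols were matched by Ensembl ID for 37607 of the 39179 genes, and coordinates come from GENCODE M21 (GRCm38), also by Ensembl ID.

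In 11 deposited columns every gene held at least a constant between 1 and 16. These were treated as a score and not as raw counts as the authors deposited them, and were left out: 9 anterior and 1 posterior column at 18 months and 1 posterior column at 3 months. No 2 columns were identical.

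Groups were taken from the titles. In 85 position-titled cells the title says 18 while the age field says 3 months. All 85 have a digit 3 in the chip position within the title, and none of the other 135 position-titled cells of that age has one. These cells were grouped by title, with leaving them out and grouping by the age field as alternatives. Title numbers 1 and 2 mark blocks of the chip and were used only as subsets of cells. Since each age was 1 pool of 6 mice and no animal is named, each group is 1 sample, and no test was run on cells.

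Cells with at least 500 genes counted were kept, 188 in the position set and 73 in the barcode set. Counts were summed per group and divided by the total count to give CPM. Log2 ratios have 1 CPM added to both sides. Intervals are 95% exact and belong to the ratio without the added CPM. The position set is the main one, because it holds all 4 groups, and the sets were never summed together. The design asked for fibroblast-like cells where both groups hold at least 10, and otherwise for all kept cells. No group of the position set reached 10, so all kept cells were used.

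Genes were named by a rule fixed before the data were examined. A gene needed at least 50 CPM in the higher group, a count in at least 25% and at least 5 of its cells, no cell with over 50% of the counts, and a 2-fold ratio the same way in summed CPM and in the mean of per-cell CPM. The share of cells with a count and the ratios within title numbers 1 and 2 had to go the same way. The 12 highest and 12 lowest ratios were named, without mitochondrially encoded, ribosomal protein, predicted or unnamed genes. The rule was met by 31 higher and 20 lower genes for region at 3 months, 5 and 33 for region at 18 months, 14 and 47 for age in anterior and 20 and 13 for age in posterior meninges. The numbers say how many were available to name and are no count of changed genes.

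The 28 gene lists and 17 marker lists were fixed at the same time. Members at 10 CPM or more in either group were measured. A list's median log2 ratio was set against 10000 random lists of the same size, drawn within 20 bins of mean expression, as a description of these libraries. The lists discussed lie under percentile 2.5 or over 97.5, with the patterning, retinoic acid and immediate early lists in any case. Some of the cell type lists between these percentiles are given as well, chosen after their values were seen, and others, such as lymphocyte and Schwann cell markers, are not discussed. Examples are from the 2 highest and 2 lowest members at 50 CPM or more, and some members are not reported here. No member of the choroid plexus list was measured.

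Cells were clustered within each library set with scanpy 1.11.5 (genes counted in at least 10% of cells, 1000 variable genes, 15 principal components, 10 neighbours, Leiden resolution 1). A cluster was named from at least 3 fixed markers raised 2-fold and counted in at least 25% of its cells, with no other class holding more markers among its top 10 genes. Earlier versions of the clustering, 2 in all, were looked at with group counts in view. A first with other variable genes was replaced because scattered genes led its clusters. A second also left out kinases whose symbols start like ribosomal proteins. The settings and the naming thresholds were set after these views, and a marker among the top 10 was then required only of clusters whose median depth was far under that of the set. The choice to leave out the 11 columns and to try totals without satellite genes came after the files were seen. No doublet caller was used, and 0 cells held at least 50% of the markers of a second class among fibroblast, endothelial, pericyte and macrophage.

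For shares of cells with a count, each cell was thinned without replacement to 4500 counts (14000 in the barcode set), and shallower cells were left out. TMM factors came from edgeR 4.0.16 in R 4.3.3, applied to group sums with no test. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

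The naming rule was tested on simulated counts over 39179 genes with 200 changed genes. It recovered 96.7% and 100% of 4-fold and 8-fold changes for region at 18 months and 100% and 98.4% for age in posterior meninges, and 37.0% and 26.8% of 2-fold changes. For region at 3 months it recovered 50.0% and 82.1% of the 4-fold and 8-fold changes and also named 25 unchanged genes. For age in anterior meninges it recovered 61.4% and 80.8% and named 23 unchanged genes. The comparisons without the 15 anterior 3-month cells named 2 and 3 unchanged genes. Only genes at 50 CPM or more could be named, so these are no rates over all 39179 genes. Whether the recovery carries over to the deposited cells was not tested. Their log2 ratios correlated at only -0.018 to 0.17 between the title numbers. In separate draws of Poisson counts, the counting intervals covered the simulated ratio for 94.7% to 97.1% of 340 genes. Exact intervals reach about their set 95% on such counts by construction, so this says nothing of the spread between cells.

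Alternatives changed 1 choice at a time: the grouping of the 85 cells, mean per-cell CPM, thinned sums, TMM or median-of-ratios scaling, cell filters, Leiden resolution 0.5 or 2, a limit of 20 or 100 CPM, 10 CPM added, 1 title number alone, the deepest cells left out, and the barcode set. Added after the data were seen were the 11 columns with the constant subtracted, totals without satellite or mitochondrial genes, cells without the smooth muscle-like and macrophage-like classes, the earlier clusterings, and lists within 1 title number.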

Results

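Single cells from the leptomeninges (the pia and arachnoid, the thin membranes on the brain surface) of C57BL/6 mice were profiled by RNA sequencing on the ICELL8 system, which dispenses cells into the wells of a chip. Cells came from the meninges over the anterior or the posterior cortex, at 3 or 18 months of age. Each age was 1 pool of 6 male mice, and the labels name no animal, so each of the 4 groups is 1 sample with no replicate. No p-value, standard error or count of changed genes can be drawn from the cells. The 472 cells fall into 2 library sets. In the larger set the title gives the position on the chip, and this set holds all 4 groups. In the other the title gives a barcode, and no anterior 18-month cell is among them. The labels do not say whether the 2 sets share a cell suspension, so the same direction in both is no independent check. Named genes, ratios and CPM (summed counts scaled to an equal total) are from the position set unless the barcode set is named.

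Of the position-titled cells, 15 anterior and 49 posterior cells at 3 months, and 57 anterior and 67 posterior cells at 18 months, had at least 500 genes with a count and were kept. Their summed counts were 576462, 1809698, 2641677 and 2319406. Kept cells had median totals of 14015, 15755, 20433 and 19338 counts, with single cells between 1221 and 311211. The barcode set kept 16 anterior and 18 posterior cells at 3 months and 39 posterior cells at 18 months, with median totals of 24489, 34163 and 39283. In the position set, 13 predicted genes that match satellite repeats took 64.4% and 66.2% of the summed counts at 3 months (anterior, posterior) and 72.2% and 65.7% at 18 months. Gm10800 alone took 39.2% to 44.2%. Whether these counts come from RNA or from genomic DNA was not tested, and genomic DNA would also add to the totals behind each CPM and to genes with few counts. In the barcode set these genes took at most 0.00147%, and mitochondrially encoded genes took 22.1% to 25.3%, against 2.03% to 3.16% in the position set. Intervals below are 95% exact intervals (Poisson for a sum, conditional binomial for a ratio, Clopper-Pearson for a share). They cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules.

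Cells of the position set formed clusters with the markers of smooth muscle (24 cells, led by Acta2, Csrp1 and Tagln), macrophages (22 cells, led by C1qc, Ccl12 and H2-Aa), endothelium (30 cells, led by Vcam1, Slc38a5 and Edn1, with the marker Slco1a4 among the top genes) and pericytes (7 cells, led by Rgs5, Ccl19 and Ccl11). The other cells stayed unnamed: 6 of 15 anterior and 25 of 49 posterior cells at 3 months, and 31 of 57 and 43 of 67 at 18 months. An unnamed cluster of 30 cells, led by Fanca, Vmn1r121, Muc5b and Abca14, had a median of 116408 counts, 6.36 times that of the set. Only 1 fixed marker, the neuron marker Syt1, was raised in its best class. Sums over all kept cells weigh such deep cells more than others. Whether their counts come from RNA or from genomic DNA was not tested. No cluster of this set had 3 or more fibroblast markers raised, so the share of fibroblast-like cells was 0 of 67 in the posterior 18-month group and 0 in the other groups. With so many cells unnamed, this does not show that fibroblasts were absent. In the barcode set, 14 cells formed a fibroblast-like cluster with raised Col1a1, Col1a2 and Igfbp5, led by Slc4a10, a bicarbonate transporter, Snhg11 and Slc26a7. It held 12 of 39 posterior 18-month cells (30.8%, interval 17.0% to 47.6%), 1 of 18 posterior 3-month cells and 1 of 16 anterior 3-month cells. At Leiden resolution 2 it held 10 of 39, 0 of 18 and 0 of 16 cells, and at resolution 0.5 no cluster was fibroblast-like. A cluster mostly of 1 group may mark that group's library and not a cell type. No class held 10 cells in each of 2 compared groups of the position set, so the comparisons below sum all kept cells of a group, whatever their class.

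The first comparison asks how the 2 regions differed at 18 months, which bears on whether adult leptomeninges are regionally patterned. Ptgds, which encodes the prostaglandin D2 synthase that meningeal cells secrete, had 4856 CPM in posterior and 370.98 CPM in anterior cells, a log2 ratio of anterior to posterior of -3.71 (interval -3.81 to -3.62). Nnat, an imprinted gene for a small membrane proteolipid, had 159.1 CPM in posterior cells (counted in 21 of 67) and 1 count in anterior cells, a log2 ratio of -6.86 with an interval of -14.02 to -6.23. Prg4, which encodes the lubricant proteoglycan lubricin, had 137.5 CPM against 15.9 CPM in anterior cells (-3.04, -3.61 to -2.65). By mean per-cell CPM its log2 ratio was smaller, at -1.217. The contractile genes Myl9 and Acta2 had log2 ratios of -3.004 (-3.28 to -2.78) and -2.65 (-2.85 to -2.47). Vwf, the von Willebrand factor of endothelial cells, went the other way, with 134.8 CPM in anterior and 48.7 CPM in posterior cells (1.449, 1.159 to 1.79). Endothelial-like cells were 15 of 57 anterior and 8 of 67 posterior cells, so the Vwf ratio was not separated from the cell types sampled.

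In the GRCm38 (mm10) build, Ptgds lies on chromosome 2 at 25466709 to 25470046 and Nnat on chromosome 2 at 157560078 to 157562522, inside Blcap on the opposite strand. Prg4 lies on chromosome 1 at 150449412 to 150466165 and overlaps Tpr. Acta2 lies on chromosome 19 at 34241090 to 34255590 and Vwf on chromosome 6 at 125546774 to 125686679. The sources used here do not say whether counting used the strand, so reads of overlapping genes may be shared. Among the other genes lower in anterior cells were Calr, an endoplasmic reticulum chaperone (-3.07), the lysosomal protease Ctsb (-2.61), Rab14 (-2.47), the mitochondrial ADP/ATP carrier Slc25a4 (-2.42), the glycolytic enzyme Aldoa (-2.41), the matrix glycoprotein Sparc (-2.40) and Apoe, a lipid carrier (-2.37, 91.6 against 478 CPM). The naming rule gave only 5 genes higher in anterior cells. Besides Vwf these were the pseudogene Fau-ps2 (2.77-fold), which resembles the mRNA of Fau, the myosin light chain Myl12b (1.396), the selenoprotein Selenow (79.1 against 35.4 CPM) and the peptide-amidating enzyme Pam (1.118). Myl12b turned to -0.38 when the cells with conflicting ages were left out.

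Markers of several cell types were lower in anterior 18-month cells. Members of a list are counted as higher or lower only where they differed at least 2-fold. All 6 smooth muscle markers were at least 2-fold lower, among them Tagln (-1.82) and Myh11 (-2.18), and their median log2 ratio of -2.25 lay at percentile 0.27 of random lists matched on expression. Of 8 measured macrophage markers 7 were at least 2-fold lower (median -2.92, percentile 0.01), including Lyz2 (-1.92), C1qb (-2.77), C1qc (-4.23) and Pf4 (-5.48). Macrophage-like cells were 4 of 57 anterior and 7 of 67 posterior cells, so this list was not separated from the cell types sampled. All 4 measured globin genes were lower in anterior cells (Hba-a2 -5.25, Hba-a1 -5.41, Hbb-bs -7.60; median -6.06, percentile 0), and Hbb-bt had no anterior count. A single posterior cell held 80.9% to 86.7% of each globin's counts. Of 18 glycolysis and hypoxia genes 11 were at least 2-fold lower and 1 was higher (median -1.44, percentile 0.42). Pfkl (-3.79) and Bnip3 (-4.76) were the lowest of them at 50 CPM, and 79.7% and 94.02% of their counts came from 1 cell. Pkm had a log2 ratio of -0.37 and Ldha of -0.66. Of 7 arachnoid-associated genes 5 were at least 2-fold lower (median -2.20, percentile 0.315), and Ptgds was the only one at 50 CPM or more.

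Medians of the lists examined for regional identity lay within those of matched random lists at 18 months. A list's median stays near its background when members move in opposite directions. It therefore cannot show whether patterning factors differ by region. The 23 measured patterning transcription factors split into 7 at least 2-fold higher in anterior cells and 9 lower (median -0.28, percentile 46.2). Prrx1, a mesenchymal homeobox gene, was higher in anterior cells (2.88, interval 2.274 to 3.98) and Nr2f2 too (1.74). Only 5 of 14 retinoic acid genes were measured (median -0.55, percentile 35.9). Of 16 immediate early genes 4 were at least 2-fold higher and 1 lower (median -0.20, percentile 80.4), with Klf4 at 2.01 and Atf3 at -0.74. Endothelial markers had a median of 0.38 (percentile 92.8), with Slco1a4 at 1.74 and Ly6c1 at -1.58. Rgs5, a pericyte marker, stood at 4.35, but 1 cell gave 76.4% of its counts. Fibroblast markers had a median of -0.24, with Col1a2 at -2.62 and Igfbp5 at -2.63.

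**Figure D1:**
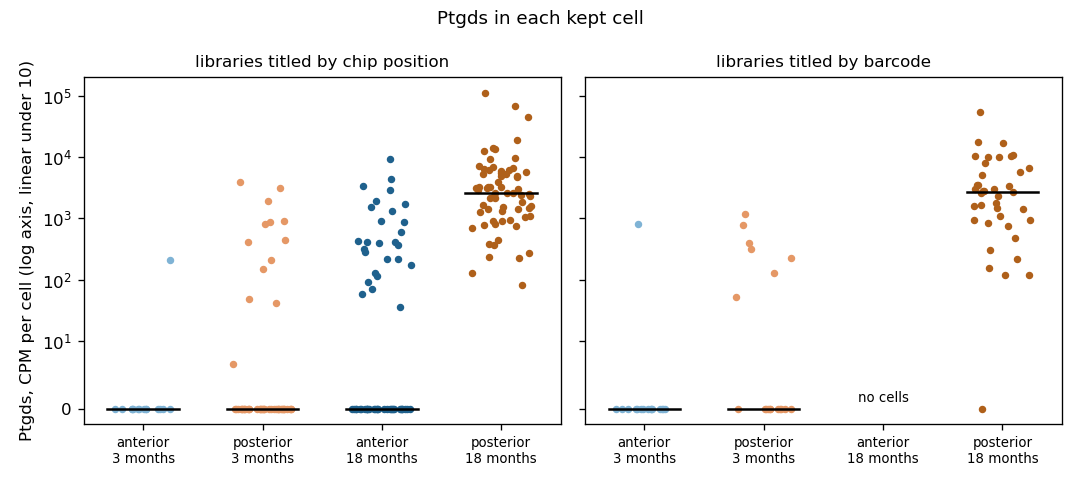
Ptgds in each kept cell, in CPM on a log axis that is linear under 10, by group for the position-titled (left) and barcode-titled (right) libraries; each point is a cell and each bar the group's median. A count for Ptgds was present in 67 of 67 and 38 of 39 posterior 18-month cells, and in 1 of 15 and 1 of 16 anterior 3-month cells.

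Ptgds was counted in 67 of 67 posterior 18-month cells (interval 94.6% to 100%), 27 of 57 anterior 18-month cells (34.0% to 61.0%), 13 of 49 posterior 3-month cells (14.9% to 41.1%) and 1 of 15 anterior 3-month cells (0.168% to 31.9%). After each cell was thinned to 4500 counts, the shares were 98.4%, 42.3%, 19.0% and 7.14%, with 5, 5, 7 and 1 shallower cells left out. Among barcode-titled cells, 38 of 39 posterior 18-month cells, 7 of 18 posterior 3-month cells and 1 of 16 anterior 3-month cells had a count. Macrophage-like cells, a class that should not make this enzyme, served as background. All 7 such posterior 18-month cells of the position set had Ptgds, at a median of 6698 CPM, against 2557 CPM in the other 60 cells. Their median depth was 11794 counts, against 20883 in the others. In anterior 18-month cells Ptgds was counted in 3 of 4 macrophage-like and 24 of 53 other cells, in posterior 3-month cells in 2 of 9 and 11 of 40, and in anterior 3-month cells in 1 of 2 and 0 of 13. The share of cells with Ptgds was therefore not shown to be above background in any group. The background class is mixed: at Leiden resolution 2 only 4 posterior and 1 anterior cell at 18 months and 5 and 1 at 3 months were macrophage-like, and Lyz2 was counted in 7 of 7, 2 of 4, 6 of 9 and 2 of 2 of the macrophage-like cells above.

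At 18 against 3 months in the posterior meninges, the comparison that asks how these cells differ with age, Ptgds had 4856 CPM against 181.8 CPM (log2 ratio 4.73, interval 4.58 to 4.90). Igkc, the immunoglobulin kappa constant region made by plasma cells, had 167.7 against 6.08 CPM (4.58, 3.93 to 5.80) and was counted in 30 of 67 cells at 18 months and in 1 of 49 at 3 months. Nnat (3.55, 3.04 to 4.32) and Prg4 (3.40, 2.88 to 4.19) were higher at 18 months. Ptprc, the pan-leukocyte antigen CD45 (-2.10, -2.77 to -1.62), and Plek, a phosphoprotein of platelets and leukocytes (-1.94), were lower. Barcode libraries gave ratios of the same sign for these 6 genes: Ptgds 4.48, Igkc 7.19, Nnat 1.578, Prg4 8.52, Ptprc -2.23 and Plek -1.29. Igkc and Prg4 had no count there at 3 months.

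Other genes higher at 18 months were Ywhaq, a 14-3-3 protein (5.39, with 3 counts at 3 months and an interval of 4.50 to 8.35), Itm2c (2.688), Slc25a4 (2.6297), the neutral amino acid transporter Slc38a2 (2.555), Tspan13 (2.165), the caveola component Cavin1 (2.00), glutamine synthetase Glul (1.648) and the RNA-binding Celf2 (1.608). Lower at 18 months were Speer4c (-4.64, with 3 counts at 18 months and an interval of -7.75 to -3.86), Catsperg1 (-2.63), the sialyltransferase St3gal6 (-2.02), the phosphate carrier Slc25a3 (-1.71), Ahsa2 (-1.56), Cox7a2 (-1.56), the chaperone Hsp90aa1 (-1.34), the interferon-induced Ifitm2 (-1.28), Kmt2a (-1.16) and Mid1 (-1.13). Of the 22 named genes measured in the barcode set 15 had the same direction there, against 55.7% of 844 genes at 50 CPM or more. Itm2c, Slc25a4, Tspan13, Glul, St3gal6, Ahsa2 and Kmt2a went the other way in that set. Speer4c and Catsperg1 had no count there in posterior cells of either age.

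Solute transporter and barrier genes were higher as a list in posterior cells at 18 months. Of 29 measured members 17 were at least 2-fold higher and 2 lower (median 1.407, percentile 100), with Slc38a2 (2.555) and the efflux pump Abcb1a (2.551) highest, Slc2a1, the glucose transporter GLUT1, at 0.37, and Slco1a4 at -1.05. The barcode set gave 18 of 23 at least 2-fold higher and 3 lower (median 3.83, percentile 99.98), with Slc4a10 at 631 CPM and no count at 3 months, while Abcb1a was lower there (-1.93). Slc4a10 led the barcode fibroblast-like cluster, which held 12 of 39 posterior cells at 18 months and 1 of 18 at 3 months. The rise of the list in that set was therefore not separated from the cell types sampled. The IGF pathway list had 5 of 8 members at least 2-fold higher and none 2-fold lower (median 1.3795, percentile 98.8). Igfbp5 (2.89) and Igfbp6 (2.74) led it, and Igfbp7 stood at 0.11. The IGF list of the barcode set also had 5 of 8 at least 2-fold higher, with 1 lower (median 3.19, percentile 99.2) and Igfbp5 at 5.01. Igfbp5 was a raised marker of the barcode fibroblast-like cluster, so this too was not separated from the cell types sampled. Col1a2, a fibroblast collagen, was higher as well (2.536), although the median of 7 fibroblast markers was 0.083.

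Chemokine, granulocyte and erythrocyte lists were lower in posterior cells at 18 months in the position set, and not as lists in the barcode set. Of 11 chemokine and cytokine genes 6 were at least 2-fold lower and 2 higher (median -2.03, percentile 0.01), with Cxcl1 at -4.65, Cxcl2 at -4.25, Ccl7 at -0.96 and Ccl2 at -0.32, against a median of -0.12 (percentile 45.9) over 13 genes of the barcode set. A single cell gave 80.8% of the Cxcl1 counts. The neutrophil genes S100a8 (410.6 CPM) and S100a9 (257.5 CPM) of the 3-month cells had no count at 18 months, and 4 of 6 granulocyte or monocyte markers were at least 2-fold lower (median -4.92, percentile 0; barcode set -0.77, percentile 21.8). In barcode libraries S100a8 was instead higher at 18 months (3.83), with 96.9% of its counts in 1 cell. All 5 measured erythrocyte markers were lower (median -2.85, percentile 0), Hba-a1 by -1.37 and Hbb-bt by -3.24, with 65.5% and 83.1% of the counts in 1 cell. The barcode set showed the opposite for globins, with all 4 measured genes higher at 18 months (median 2.631). Of 16 immediate early genes 6 were at least 2-fold lower and none higher (median -0.54, percentile 1.6). Fos had a ratio of 0.99, Junb of 0.72, Klf2 of -1.72 and Klf4 of -1.75, and the list's median was 0.13 in the barcode set.

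Patterning transcription factors had 11 of 27 members at least 2-fold higher and 9 lower with age in posterior cells (median 0.27, percentile 85.6), with Foxp1 at 0.47. Retinoic acid genes had 3 of 6 at least 2-fold higher and 1 lower (median 1.1702, percentile 96.6). Neuron markers had 3 of 5 at least 2-fold higher (median 1.72, percentile 98.02), none of them at 50 CPM, and a median of -1.35 by mean per-cell CPM. Smooth muscle markers had a median of 0.84, with Des at 2.97, Myh11 at 1.20 and Acta2 at 0.78. Macrophage markers had a median of 0.15, with Mrc1 at 1.631 and Lyz2 at -1.20. Endothelial markers had a median of -0.055, with Ly6c1 at 1.172 and Flt1 at -1.44.

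**Figure D2:**
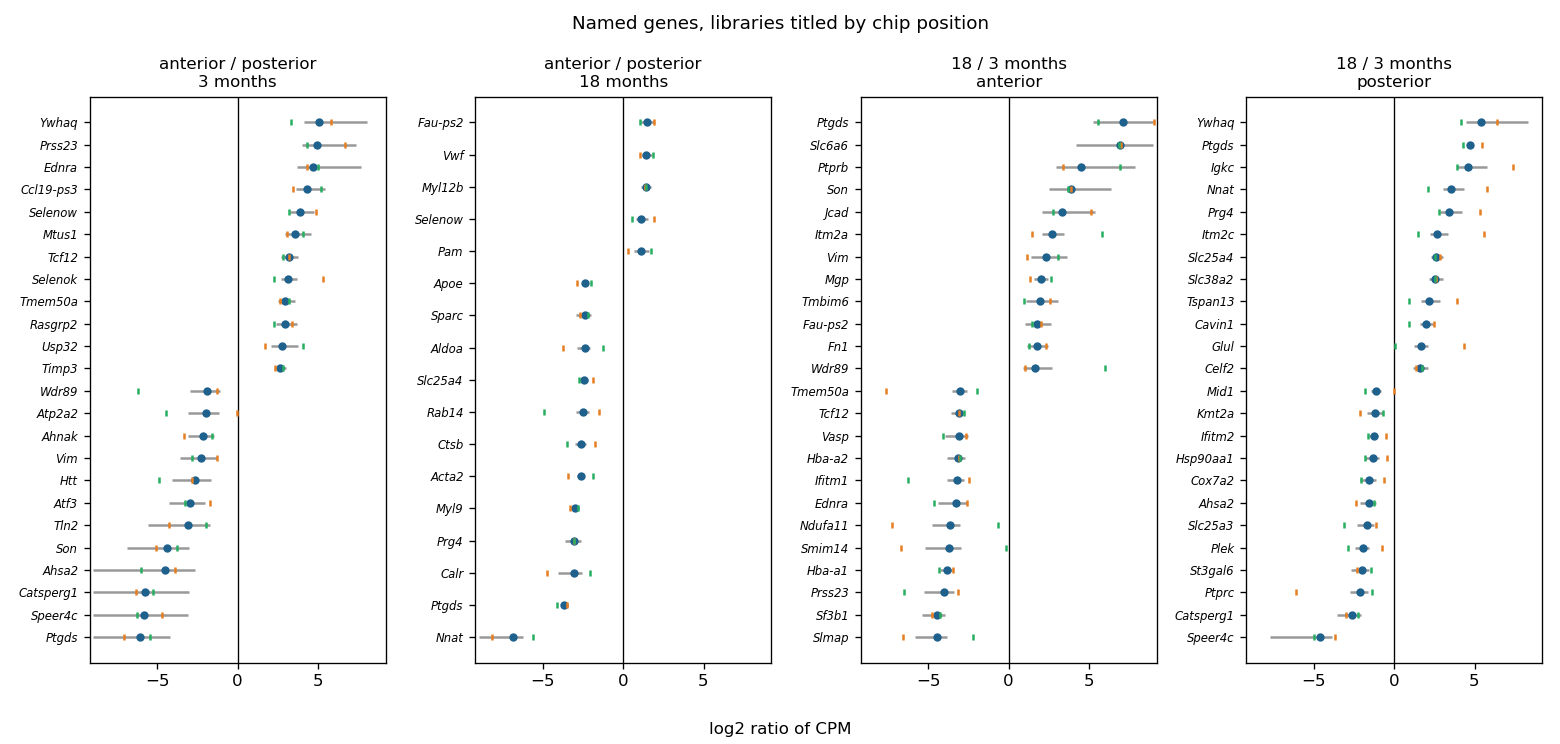
Log2 ratios of CPM of the named genes in the 4 comparisons of the position-titled libraries. Dots are ratios of the summed counts with 1 CPM added, grey lines are 95% counting intervals of the ratio without it, clipped to the axis, and orange and green ticks are the ratios within the cells of title number 1 and title number 2. At 18 months 5 genes lie above 0 and 12 below.

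In the anterior meninges, the age comparison rests on 15 cells at 3 months, of which 2 held 199661 and 175372 of the 576462 summed counts and so weigh heavily on each ratio with this group. Ptgds had 370.98 CPM at 18 months and 1 count at 3 months (log2 ratio 7.09, interval 5.26 to 13.05). Slc6a6, the taurine transporter, had 118.9 CPM at 18 months and no count at 3 months. Set against a floor of 3 counts over the group it was 22.8-fold higher, and the lower interval bound of its log2 ratio was 4.21. The endothelial genes Ptprb (4.49, 2 counts at 3 months, 2.97 to 7.89) and Jcad (3.31) were higher at 18 months. So were the matrix genes Mgp, an inhibitor of calcification (1.99, 1.587 to 2.457), and Fn1, fibronectin (1.73), with Itm2a (2.671), vimentin Vim (2.308), the splicing protein gene Son (3.86, 3 counts at 3 months, 2.531 to 6.38), Tmbim6 (1.95), Fau-ps2 (1.74) and Wdr89 (1.664). Grouped by the age field, 6 of these genes turned: Slc6a6 -0.58, Ptprb -0.39, Itm2a -0.18, Vim -0.45, Mgp -0.40 and Fau-ps2 -0.60. If the titles are right, the age field puts cells of 18 months into the 3-month group. Age ratios then shrink by construction, so these turns are no check of the genes. Lower at 18 months were Slmap (-4.48), the splicing factor Sf3b1 (-4.47), the serine protease Prss23 (-4.05), Smim14 (-3.69), Ndufa11 (-3.67), the endothelin receptor Ednra (-3.28), Ifitm1 (-3.23), the actin regulator Vasp (-3.10), Tcf12 (-3.09) and Tmem50a (-3.01). The globin genes Hba-a1 (-3.86) and Hba-a2 (-3.17) are near-identical copies whose reads can be shared.

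Across lists in the anterior age comparison, the median of all genes at 10 CPM was -0.57, and the matched random lists also had medians under 0, so percentiles near 100 mark lists that stayed above this shift. Endothelial markers did so with 6 of 8 at least 2-fold higher (median 1.73, percentile 99.6), such as Slco1a4 (2.309) and Flt1 (1.266), with Tek at -1.13, and endothelial-like cells were 15 of 57 anterior cells at 18 months and 1 of 15 at 3 months. Collagens had 8 of 16 at least 2-fold higher and 3 lower (median 1.635, or 1.08 with zero counts at the floor, percentile 99.2), but the only 2 at 50 CPM, Col3a1 (-1.78) and Col5a2 (-2.82), were lower. Proteoglycans and matrix glycoproteins had 8 of 21 at least 2-fold higher and 8 lower (median 0.84, percentile 99.5), with Mgp and Fn1 higher and Postn (-4.91) and Aspn (-5.30) lower. MHC class II had 2 of 6 at least 2-fold higher (median 0.90, percentile 99.6), and 1 cell gave 91.96% of the H2-Aa counts. Within title number 1 the median of MHC class II was -3.28 (percentile 4.97). MHC class I had 4 of 11 at least 2-fold higher and 4 lower (median 0.48, percentile 99.4, and -0.33 without the cells of conflicting age), with Psmb8 at 1.511, H2-Q7 at 1.06, H2-T23 at -1.50 and B2m at -1.81. Dura-associated genes had 3 of 7 at least 2-fold higher (median 0.84, percentile 97.8), with Mgp and Fxyd5 (1.111) first and Foxp1 at 0.20.

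Housekeeping lists lay above the random lists with medians near 0: oxidative phosphorylation (26 genes, 6 at least 2-fold higher and 5 lower, median -0.13, percentile 99.1, Atp5j 2.04), cytosolic ribosomal proteins (24 genes, 5 and 5, median -0.30, percentile 99.5, Rps20 2.94 and Rps29 -2.41) and mitochondrially encoded genes (11 genes, none past 2-fold, median 0.30, percentile 99.8, mt-Nd5 0.83 and mt-Nd6 -0.44). With TMM scaling the oxidative phosphorylation and ribosomal medians were 0.69 (percentile 89.99) and 0.54 (percentile 92). Both then lay within those of matched random lists. Immediate early genes had 7 of 16 at least 2-fold higher and 2 lower (median 0.27, percentile 99.95), with Klf4 at 2.09 and Fosl2 at -2.19, but a median of -0.47 by mean per-cell CPM. All 3 measured globins were lower (median -3.86, percentile 1.94). Patterning transcription factors had 9 of 20 at least 2-fold higher and 8 lower (median 0.070, percentile 79.8), with Lef1 at 66.2 CPM and no count at 3 months, Prrx1 at 1.798, Foxc1 at -4.04 and Tbx15 at -4.36. Retinoic acid genes had a median of -1.40 (percentile 26.2). Smooth muscle markers had a median of -1.50 (Tagln -2.31, Myl9 -2.88), pericyte markers of -1.85 (Rgs5 -1.40, Vtn -1.92) and macrophage markers of -1.39 (Lyz2 -2.99).

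At 3 months, the region comparison sets the same 15 anterior cells against 49 posterior cells. Ptgds had 181.8 CPM in posterior cells and 1 count in anterior cells (log2 ratio -6.06, interval -12.02 to -4.22). Ednra, which encodes the endothelin A receptor of vascular smooth muscle, had 67.7 CPM in anterior cells and 3 counts in posterior cells (4.69, 3.70 to 7.69). Prss23 (4.93, 4.02 to 7.38), Ywhaq (5.07, 3 posterior counts, 4.11 to 8.06) and Timp3, an inhibitor of matrix metalloproteases that lies inside Syn3 (2.617, 2.295 to 2.99), were also higher in anterior cells. Atf3, a stress-induced transcription factor, was lower (-2.95, -4.27 to -2.03). Other genes higher in anterior cells were the chemokine pseudogene Ccl19-ps3 (4.33), whose reads can be shared with Ccl19, Selenow (3.86), Mtus1 (3.58), Tcf12 (3.17), Selenok (3.11), Tmem50a (2.97), Rasgrp2 (2.96) and Usp32 (2.78). Lower in anterior cells were Ahsa2 (-4.55, 1 anterior count, -10.50 to -2.68), Son (-4.37, 3 anterior counts, -6.90 to -3.05), Tln2 (-3.08, 3 anterior counts, -5.61 to -1.71), Htt (-2.64), Vim (-2.26), Ahnak (-2.16), Atp2a2 (-1.97) and Wdr89 (-1.90). Speer4c and Catsperg1 had 56.4 and 53.0 CPM in posterior cells, near the 50 CPM limit, and no anterior count. Set against a floor of 3 counts over the group they were 10.8-fold and 10.2-fold lower, and the upper interval bounds of their log2 ratios were -3.11 and -3.02. Neither gene had a count in kept 3-month cells of the barcode set.

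Of the 20 named genes of the 3-month region comparison that the barcode set measured, 9 had the same direction there, against 50.4% of 1161 genes at 50 CPM or more, so this set did not bear these genes out as a group. Ptgds (-1.39), Ednra (2.587), Prss23 (0.89), Selenok (2.148), Rasgrp2 (1.192), Usp32 (3.65), Tln2 (-4.07), Atf3 (-0.66) and Son (-0.13) kept their sign. Pericyte markers had 4 of 6 at least 2-fold higher in anterior cells (median 2.427, percentile 96.2), with Vtn at 5.66 and Rgs5 at 5.44. Pericyte-like cells were 4 of 15 anterior and 1 of 49 posterior cells at 3 months, so these values and that of Ednra were not separated from the cell types sampled. Macrophage markers had 4 of 9 at least 2-fold lower and 1 higher (median -0.83, percentile 1.335), with C1qc at -5.88 and Lyz2 at -0.13, and a median of 0.33 within title number 1. Random lists matched to these markers had a median of 0.75. Barcode libraries had 5 of 8 macrophage markers at least 2-fold lower (median -7.13, percentile 0). Endothelial markers had 4 of 7 at least 2-fold lower (median -1.62, percentile 0.82), with Flt1 at -2.83, and granulocyte or monocyte markers 5 of 6 at least 2-fold lower (median -5.25, or -2.83 with zero counts at the floor, percentile 0), with S100a8 at -6.52. All 5 measured erythrocyte markers were lower (median -3.35, percentile 0.06), with Hba-a1 at -2.93, and 1 posterior cell gave 93.9% of its counts. The barcode set had the erythrocyte list the other way (median 1.93, 2 of 4 at least 2-fold higher and none 2-fold lower).

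Immediate early genes were lower in anterior cells at 3 months in both library sets, with 6 of 16 at least 2-fold lower and 2 higher in the position set (median -0.54, percentile 0.16) and 8 of 18 at least 2-fold lower in the barcode set (median -0.79, percentile 1.7). By mean per-cell CPM the median of the position set turned to 0.31 (percentile 45.1). Klf2 (-4.56) and Atf3 (-2.95) were lowest, and Fosl2 (2.363) and Jun (1.403) were higher. Glycolysis and hypoxia genes had 6 of 16 at least 2-fold lower and 4 higher (median -0.64, percentile 2.05), with Eno1 at -2.67 and Higd1a at 3.70. This direction turned in the barcode set (median 0.31), over members at 50 CPM (0.13) and within title number 1 (0.37). Cytosolic ribosomal proteins had 6 of 24 at least 2-fold lower and 1 higher (median -0.014, percentile 0.99), with Rplp0 at -2.83 and Rps29 at 1.73, and a median of 0.52 within title number 1. Mitochondrially encoded genes had a median of -0.39 (percentile 1.5), with mt-Nd3 at -1.26 and mt-Co1 at 0.46, and of 0.24 in the barcode set. Random lists matched on expression lay above 0 in the position set. Their medians were 0.84 for immediate early, 0.67 for glycolysis and hypoxia, 0.81 for ribosomal and 0.70 for mitochondrially encoded genes. Low percentiles here therefore mark lists that stayed below this shift, and do not by themselves show lower expression in anterior cells. Patterning factors had 9 of 22 at least 2-fold higher and 10 lower (median -0.27, percentile 46.5), with Foxc1 at 3.20, Tbx15 at 2.481 and Nr2f2 at 1.95, and 72.7% of the Foxc1 counts came from 1 cell. Of 5 measured retinoic acid genes 3 were at least 2-fold higher (median 1.73, percentile 90.1).

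Across 594 genes at a mean of 50 CPM or more, the anterior to posterior log2 ratios at 3 and at 18 months had a Pearson r of 0.22 and a Spearman rho of 0.068. Within title number 1 this r was 0.057 and within title number 2 -0.033. The age ratios of the 2 regions had an r of 0.15 and a rho of 0.11. Genes are not independent replicates, so no p is given. Summed Ptgds counts were higher in posterior cells at both ages, and higher at 18 months in both regions, as differences between whole groups of wells that were not separated from the background in macrophage-like cells. The same correlation between the cells of title number 1 and title number 2, for which the labels do not say whether they share a suspension, was 0.0046 for region at 3 months, 0.17 for region at 18 months, -0.018 for age in anterior and 0.14 for age in posterior meninges. Position and barcode libraries had an r of 0.19 for region at 3 months and 0.095 for age in posterior meninges over 471 genes. Gene ratios were therefore correlated weakly or not at all between these subsets of cells. The median log2 ratio of the 594 genes was 0.35 and -0.43 for region at 3 and 18 months and -0.74 and 0.18 for age in anterior and posterior meninges. TMM scaling shifts these medians by -0.53, 0.13, 0.84 and 0.18.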

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

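The tests of fibroblast markers, of the 85 conflicting cells and of smooth muscle genes were chosen after related values had been seen. The tests of free RNA and of depth for Ptgds were written before their results.

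Ptgds in wells outside the comparisons came up because those wells held a signal. Of posterior 18-month wells with under 500 genes, 82.2% in the position set and 92.9% in the barcode set had a Ptgds count, against 11.8% and 47.4% of such posterior 3-month wells. Some anterior wells of this kind held it too. Among barcode-titled 3-month wells their share was about that of the posterior wells, unlike in kept cells. Within kept cells the gene was counted in every macrophage-like posterior 18-month cell. Deeper libraries are argued against, since after thinning 98.4% of posterior 18-month cells had Ptgds, against 19.0% at 3 months. Free Ptgds RNA in the posterior 18-month suspension is a candidate explanation: the median per-cell CPM in macrophage-like cells was 2.6199 times that of the other cells in the position set and 2.219 times in the barcode set (2 macrophage-like cells), where cells lacking the gene should be far lower. The ratio was between 1.07 and 3.95 under the other clusterings and cell filters. The 5 macrophage-like cells of the barcode set had a median of 98453 counts, 2.6 times that of the set. In the position set this class was shallower than the set, and the ratios do not account for depth. A larger share of fibroblasts or more of their RNA stays open, with a median log2 ratio of fibroblast markers of 0.083 in the position set and 0.88 in the barcode set. Free RNA and more of the source RNA do not exclude each other, and age itself was not tested, since each age is 1 pool.

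The age field of 3 months on the 85 cells titled 18 was weighed next. An origin in the 3-month mice is argued against, because 92.6% of the 54 posterior conflicting cells (interval 82.1% to 97.9%) had Ptgds, against 19.0% of posterior 3-month cells and 93.1% of the posterior cells whose labels agree. A fill of the age field keyed to a digit 3 in the chip position may account for the conflict, since 0 of the 220 cells titled 18 break that pattern. No biological explanation was tested.

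Smooth muscle genes were lower in anterior than posterior cells at 18 months, with a median log2 ratio of -2.25. Satellite counts in the totals are argued against as the whole cause, since the median was -1.99 with satellite genes left out. That shift is about the same for every gene and followed from the satellite shares, so its size was known beforehand. Whether genomic DNA added to the counts of these genes was not addressed by it. A smaller share of smooth muscle cells stays open: smooth muscle-like cells were 6 of 57 anterior and 8 of 67 posterior cells, against 1 of 57 and 8 of 67 at Leiden resolution 2, 0 of 56 and 6 of 66 with a mitochondrial filter, and 3 of 57 and 9 of 67 or 6 of 57 and 7 of 67 in earlier clusterings. A lower level per cell stays open too, since Acta2 had a median of 2303 CPM in the 6 anterior and 12635 CPM in the 8 posterior smooth muscle-like cells, a class whose members depend on the clustering, and without this class the list's median was -0.89. Region as a biological explanation was not tested.

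The next genes had opposite signs in 2 contrasts, in both title numbers, which the naming rule partly required, and the differences were not tested. The log2 ratio of anterior to posterior at 3 months minus that at 18 months was 7.50 for Prss23, 5.24 for Sparc, 4.41 for Tmem50a, 6.41 for Ywhaq and -8.08 for Speer4c. The ratio of 18 to 3 months in anterior minus that in posterior cells is the same difference with its sign turned, and no second observation. It was -5.20 for Ednra, -7.50 for Prss23, 8.08 for Speer4c and -4.41 for Tmem50a. In the barcode set the 3-month ratio turned for Ywhaq (-0.53) and Tmem50a (-1.33), and Speer4c had no count in either 3-month group. Speer4c had no count in anterior 3-month cells, and all of these rest on the 15 anterior cells at 3 months.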

How the results depend on the processing

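The tests within 1 title number for lists, the columns with the constant subtracted, the totals without satellite or mitochondrial genes, the cells without named classes and the earlier clusterings were chosen after the data were seen. No paired analysis was possible because each group is 1 sample and no test was run. The comparisons over all kept cells use no clusters, so the other Leiden resolutions left their values unchanged by construction, while the shares of classes moved with the resolution. The named genes were chosen for the same direction by mean per-cell CPM and in both title numbers, so their direction there was fixed by the choice. Of 24, 17, 24 and 24 named genes, the number with the same direction and a 2-fold ratio stayed within 1.5 times under every alternative except these. For region at 3 months it was 6 in the barcode set and 12 with a 100 CPM limit. For age in anterior meninges it was 15 by the age field and 12 with the 100 CPM limit. For age in posterior meninges it was 14 by the age field, 11 in the barcode set and 13 with the limit. The correlation of region ratios at the 2 ages was 0.15 without the conflicting cells, 0.14 with mean per-cell CPM, 0.14 with thinned sums, and 0.057 and -0.033 within title numbers 1 and 2. The fibroblast-like share of posterior 18-month cells was 30.8% in the barcode set (25.6% at resolution 2 and none at 0.5) and 0 under each other alternative. The causes were not tested, except that the higher limit removes genes by construction.

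Directions turned for the next genes and lists, whose cause was not tested. In the barcode set, region at 3 months gave Ywhaq -0.53, Ccl19-ps3 -2.11, Selenow -0.32, Mtus1 -6.47, Tcf12 -0.51, Tmem50a -1.33, Timp3 -1.67, Vim 1.164, Ahnak 0.10, Atp2a2 0.39 and Wdr89 0.12, and age in posterior meninges gave Itm2c -2.38, Slc25a4 -0.18, Tspan13 -0.29, Glul -0.42, St3gal6 2.245, Ahsa2 7.12 and Kmt2a 1.513. Medians of lists there were 0.31 for glycolysis and hypoxia, 0.24 for mitochondrially encoded genes and 1.93 for erythrocyte markers (region at 3 months), and 0.13 for immediate early genes and 2.631 for erythrocyte markers (age in posterior meninges).

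Grouping by the age field gave Catsperg1 0.15 for region at 3 months, and Slc6a6 -0.58, Ptprb -0.39, Itm2a -0.18, Vim -0.45, Mgp -0.40 and Fau-ps2 -0.60 for age in anterior meninges. If the titles are right, this grouping mixes cells of both ages in the 3-month groups, and such turns are no check of the genes. Myl12b at 18 months was -0.38 both by the age field and without the conflicting cells, which also turned MHC class I with age in anterior meninges (-0.33). Without a cell filter, region at 3 months gave Vim 0.019 and Wdr89 0.0945, and age in anterior meninges gave Wdr89 -0.30.

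For region at 3 months, the median of glycolysis and hypoxia genes was 0.13 over members at 50 CPM and 0.37 in title number 1. Mean per-cell CPM gave 0.31 for immediate early and 0.14 for mitochondrially encoded genes, and title number 1 gave 0.52 for ribosomal proteins and 0.33 for macrophage markers. For age in anterior meninges, MHC class I was -0.019 over members at 50 CPM and MHC class II -3.28 in title number 1. Oxidative phosphorylation was 0.69 with TMM, 0.39 without satellite genes and 1.337 in title number 2 (percentiles 89.99, 97.45 and 99.64). Ribosomal proteins were 0.54, 0.0511 and 1.04 (percentiles 92, 98.32 and 100). With TMM both lists lay within matched random lists. Immediate early genes were -0.28 over members at 50 CPM, -0.47 by mean per-cell CPM and -0.00231 with the constant columns kept after subtraction. Neuron markers with age in posterior meninges were -1.35 by mean per-cell CPM.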

Other observations

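In barcode libraries, several gene lists were higher in posterior cells at 18 than at 3 months. All 7 measured pia-associated genes were at least 2-fold higher (median log2 ratio 4.85, percentile 99.87 of matched random lists), while in the position set 2 of 8 were at least 2-fold higher and 3 lower (median -0.65, percentile 19.8). The chemokine gene Cxcl12 had 125.2 CPM and the collagen gene Col1a1 65.5 CPM at 18 months, each with no count at 3 months. S100a6 had a ratio of 5.45 and the gap junction gene Gja1 of 4.85. Growth factor genes had 11 of 17 at least 2-fold higher (median 3.30, percentile 98.96), with Ptn at 114.4 CPM and no count at 3 months. Retinoic acid genes had 7 of 8 at least 2-fold higher (median 3.95, or 2.532 with zero counts at the floor). Cyp26b1, which degrades retinoic acid, had 102.7 CPM, all from 1 cell. Dura-associated genes had 5 of 7 at least 2-fold higher (median 1.84), with Foxp1 at 2.251 and Ogn at 0.67. The fibroblast-like cluster held 12 of the 39 posterior cells at 18 months and 1 of 18 at 3 months.

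Also in the barcode set, and not in the position set, anterior cells at 3 months had fewer chemokine and complement transcripts than posterior cells. All 10 measured chemokine and cytokine genes were at least 2-fold lower (median -5.93, or -4.62 with zero counts at the floor, percentile 0). Ccl4 had 434.2 CPM and Ccl7 270 CPM in posterior cells and no count in anterior cells, and Cxcl2 stood at -3.29. Complement genes had 11 of 14 at least 2-fold lower (median -4.45, or -3.37 with zero counts at the floor), C1qc with 361.04 CPM in posterior and no count in anterior cells. Heat shock genes had 8 of 11 at least 2-fold lower (median -2.06), with Hspe1 at -4.34 and Hspa8 at -0.30. Oxidative phosphorylation genes had 14 of 28 at least 2-fold higher and 2 lower (median 1.01, percentile 98.56), with Sdhb at 5.33. This list went the other way in the position set, with 6 of 28 at least 2-fold higher and 8 lower (median -0.19, percentile 3.17). The WNT list had 5 of 5 at least 2-fold lower (median -4.87, or -3.68 with zero counts at the floor). The transporter list had 6 of 9 at least 2-fold lower (median -3.92, or -2.34 with zero counts at the floor). A single cell gave 78.1% of the C1qc counts. The position set had medians of 0.39 for chemokines and cytokines (percentile 37.4) and 0.22 for complement (percentile 28.6). Macrophage markers of the barcode set were lower with these lists (median -7.13), and its macrophage-like cells were 0 of 16 anterior and 3 of 18 posterior cells. With age in posterior cells of that set, oxidative phosphorylation genes had 14 of 28 at least 2-fold higher (median 0.83, percentile 99.8), and matrix protease genes had 7 of 14 at least 2-fold lower and 4 higher (median -1.28, percentile 2.38). In the position set matrix protease genes had 5 of 16 at least 2-fold higher and 5 lower (median 0.34, percentile 83.4). Oxidative phosphorylation genes had a median of 0.35 there (percentile 82.3).

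Mgp, a matrix protein of vessel walls and fibroblasts, was counted in 53 of 67 posterior 18-month cells of the position set and in 32 of 39 of the barcode set, against 22 of 49 and 8 of 18 at 3 months. Macrophage-like cells of the older position set had it in 6 of 7 cases. Igkc was counted in 16 of 57 anterior and 30 of 67 posterior cells at 18 months, against 0 of 15 anterior and 1 of 49 posterior cells at 3 months. Barcode libraries had it in 18 of 39 posterior cells at 18 months and in none of the 16 anterior and 18 posterior cells at 3 months. Posterior 18-month wells with under 500 genes held Igkc in 8 of 45 cases in the position set, and macrophage-like cells of that group in 0 of 7. Other classes that do not make immunoglobulin held it: endothelial-like cells in 3 of 8 and smooth muscle-like cells in 2 of 8 posterior cells at 18 months, and in 3 of 15 and 3 of 6 anterior cells.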
